A study of Homo sapiens and Mus musculus with 18 samples.

How the data were processed

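RNA was measured in 12 human libraries (MCF-7 and MDA-231 cells with control siRNA or PRMT6 siRNA) and 6 mouse libraries (wildtype and MMTV-PRMT6 mammary cells), with 3 libraries per group. Per the labels' protocols, RNA was extracted with Qiagen RNeasy from cells at passage 10 to 15, and libraries were made with the TruSeq Stranded mRNA LT kit from 0.1 to 0.2 µg of RNA, with inserts of 120 to 200 bp. The same protocol text, with its siRNA step and cell culture medium, stands on the mouse labels. Per the submitters' processing notes, FastQC, HTSeq and DESeq2 were used with the builds hg38 and mm10. The notes give no versions and do not state the aligner, the annotation release, the strand setting of the counting or any filter. The deposited values are raw read counts per gene symbol, made by the authors with HTSeq per the submitters' processing notes, with 58387 human and 24062 mouse symbols. Of the human symbols 36055 match GENCODE 29, 18587 of them protein coding, and positions are given from that release. No mouse annotation was used here, so mouse genes are given by symbol only.

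HTSeq's special tallies (not unique, no feature, ambiguous) stayed out of library sizes and tests. The share of alignments that were not unique averaged 77.2, 38.0, 51.5, 78.1, 44.5 and 25.5% in MCF-7 control, MCF-7 knockdown, MDA-231 control, MDA-231 knockdown, wildtype and MMTV-PRMT6 libraries. In the same order, unique alignments outside annotated genes made up 16.0, 13.8, 40.9, 38.9, 25.2 and 54.7% of unique alignments, and ambiguous ones 5.27, 5.81, 3.37, 3.40, 0.131 and 0.183%. Counts in genes averaged 17.6, 28.6, 17.6, 11.9, 15.8 and 17.9 M per library. Libraries with under 50% of alignments not unique are called the low class and the others the high class. Counts are not corrected for reads shared by near-identical genes, and without a stated strand setting a gene and its antisense partner cannot be told apart.

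From the counts, log2 fold changes were computed with edgeR 4.0.16 (R 4.3.3): filterByExpr, TMM scaling, and a quasi-likelihood F test on group with Benjamini-Hochberg adjustment at 0.05. Each comparison was fitted on its own 6 libraries, and the interaction on all 12 human libraries with 4 groups. The standard error is the absolute log2 fold change over the square root of F. CPM are TMM-scaled, except where they are named as shares of all gene counts or as not TMM-scaled. Gene lists fixed before the data were examined were tested with camera (limma 3.58.1) at a preset correlation of 0.01, adjusted over the lists of a comparison. They are oestrogen receptor targets, NF-κB targets and pathway members, DNA replication, mitosis, p53 targets, genes reported as repressed by PRMT6, arginine methyltransferases, interferon, mesenchymal, epithelial junction, unfolded protein response, cholesterol, hypoxia, oxidative phosphorylation, ribosomal protein and growth factor genes. Luminal and basal line markers were added for the cell lines, and milk, fatty acid, adipocyte, fibroblast, endothelium, macrophage, T cell, B and plasma cell, neutrophil, luminal epithelium, basal, muscle, skin and involution lists for the mouse. Counts of members adjusted over the list alone use the same test. Shared genes were counted among genes tested in both fits, beside the number that independent lists give (the product of the called counts over the genes tested).

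The genes named are those fixed beforehand and, by a rule set beforehand, the 10 largest rises and falls among genes past the threshold with a mean log2 CPM of at least 2 and no overlap between the groups' libraries, leaving out clone-based, predicted and pseudogene symbols. Examples of a list are among its 4 members with the smallest adjusted p per direction, examples of shared genes are those with the smallest sum of ranks of adjusted p, and for the interaction the 5 largest differences each way are named without the overlap rule. Where a group had no count, a floor of 3 counts over the group was used. Words of 7 bases were sought in the 3′ UTRs of GENCODE 29, with UTRs of at least 50 bases, against genes of like UTR length (20 bins) and GC content (5 bins) and 100 random sets. Coding transcripts within 20% in length and 5 points in GC content were held beside the PRMT6 transcript (python 3.11.15, numpy 2.4.6, figures with matplotlib 3.10.9).

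The edgeR analysis was tested on simulated data with 200 changed genes at the depth and trended spread of the libraries. Changes were placed only in genes above a minimum CPM, without spread particular to a gene or a library class. The shares below therefore do not cover genes of low counts. It recovered, of genes changed 1.5-fold and 2-fold, 99% and 100% in MCF-7 (13 of 212 calls false), 95% and 100% in MDA-231 (8 of 203 calls false), 35% and 90% in the mouse (7 of 132 calls false) and 84% and 99% in the interaction (11 of 194 calls false). The biological coefficient of variation was 3.37% in MCF-7, 5.05% in MDA-231 and 16.2% in the mouse. The labels do not state whether the libraries of a group come from separate transfections or animals. The p-values therefore measure the spread between these libraries only. Alternatives set before the data were examined were DESeq2 size factors, no low count filter, DESeq2 1.42.0, limma-voom, a replicate block, each library left out in turn, all 12 human libraries in one fit, scaling without the 20 most abundant genes, a test against a 1.2-fold change, camera with an estimated correlation, and fry. Alternatives added later were the library class as a term, the high class alone, protein-coding genes alone, the milk genes left out, and list tests on the interaction. The class term rests on MDA-231 controls 1 and 2 against control 3, and is poorly or not estimated for genes nearly unread in them. No library was left out of the results reported.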

Results

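The series measured RNA by sequencing in 18 libraries, given as read counts per gene, in 6 groups of 3. In the human part, MCF-7 cells (an established luminal breast cancer line that carries the oestrogen receptor ESR1) and MDA-231 cells (an established line that the labels call basal) had received either a control siRNA or an siRNA against PRMT6. PRMT6 is an enzyme that places methyl groups on arginines of histones and other proteins. In the mouse part, mammary cells of wildtype C57BL/6 mice stood beside cells labelled MMTV-PRMT6, a construct in which a mammary promoter drives PRMT6. Only the MMTV-PRMT6 labels state a stage, mammary tissue after lactation, and no stage is given for the wildtype. The counts assigned to genes, in M (mega) for libraries 1, 2 and 3, were 17.4, 19.97 and 15.3 for MCF-7 control, 28.99, 29.1 and 27.7 for MCF-7 knockdown, 19.7, 20.5 and 12.6 for MDA-231 control and 11.03, 11.1 and 13.7 for MDA-231 knockdown. They were 12.6, 18.3 and 16.3 M for wildtype mice and 21.1, 23.7 and 9.09 M for MMTV-PRMT6.

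The human libraries fell into 2 classes by the share of alignments that were not unique, and the classes moved with the groups. That share was 77.2% ± 4.26 (SD, n = 3) in MCF-7 control and 38.0% ± 0.987 in MCF-7 knockdown libraries. It was 38.7%, 37.1% and 78.6% in MDA-231 controls 1, 2 and 3, and 78.1% ± 2.23 in the MDA-231 knockdown. The knockdown was thus the low class in MCF-7 and the high class in MDA-231. The ribosomal RNAs of mitochondria (MT-RNR1 and MT-RNR2) took 2.80% ± 0.850 of gene counts in MCF-7 control, 0.0878% ± 0.0257 in MCF-7 knockdown, 0.490, 0.398 and 2.06% in MDA-231 controls 1, 2 and 3 and 3.50% ± 0.822 in MDA-231 knockdown libraries. Wildtype mice had 44.5% ± 2.06 and MMTV-PRMT6 mice 25.5% ± 1.97 of alignments not unique.

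**Figure D1:**
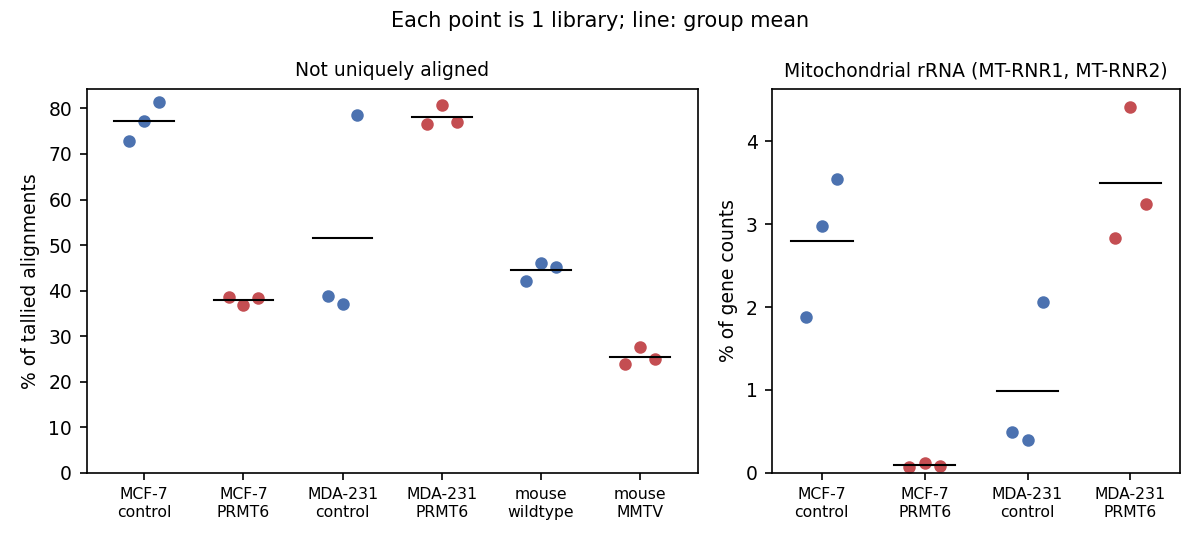
The share of alignments that were not unique in each of the 18 libraries, by group. A second panel shows the share of gene counts in the mitochondrial ribosomal RNAs MT-RNR1 and MT-RNR2 in the human libraries. Knockdown libraries have the lower share in MCF-7 and the higher share in MDA-231, where control 3 lies with the knockdown libraries.

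The targeted gene was read in every library to check the labels. PRMT6 (hg38 chromosome 1, 107056679 to 107067636) stood at 278, 276 and 260.1 scaled counts per M gene counts (CPM) in the MCF-7 controls and at 45.6, 44.6 and 42.9 CPM in the MCF-7 knockdown, a log2 change of −2.61 (SE 0.04, adjusted p 9.6e-33). In MDA-231 it stood at 19.5, 20.1 and 19 CPM in the controls and 5.47, 5.17 and 4.79 CPM in the knockdown, a change of −1.93 (SE 0.11, adjusted p 1.5e-11). Both lines therefore carried less PRMT6 RNA in each knockdown library, 6 of 6, than in any control of the line. Mouse Prmt6 stood at 10.3, 11.1 and 8.42 CPM in wildtype and 12.5, 11.1 and 11.4 CPM in MMTV-PRMT6 libraries. Its change of 0.23 (SE 0.14, adjusted p 0.178) did not pass the edgeR test, so a rise of mouse Prmt6 was not detected in these libraries. The species and sequence of the transgene are not in the labels, so whether counts of the mouse gene would hold its reads was not tested, and the libraries are called the libraries labelled MMTV-PRMT6.

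**Figure D2:**
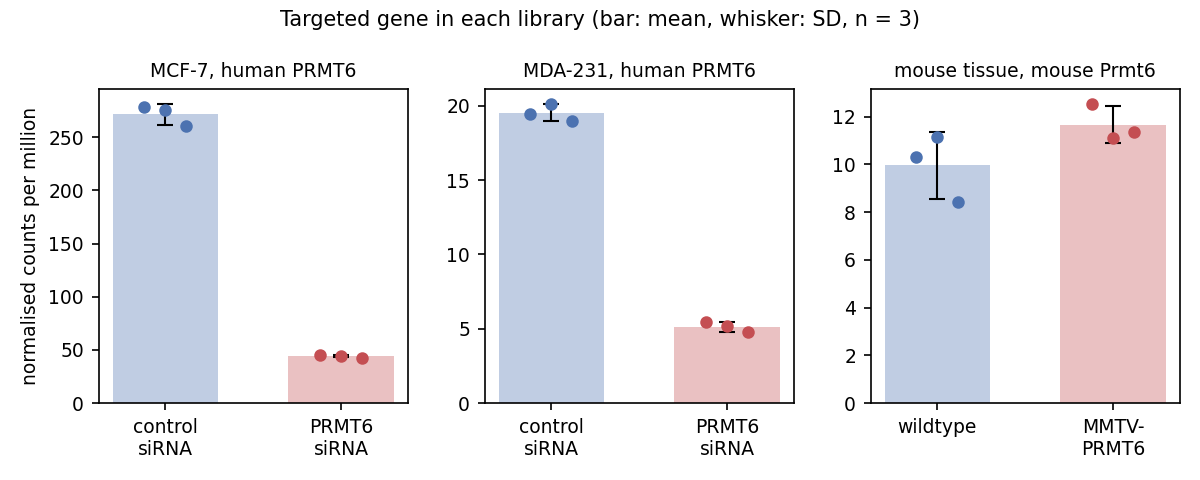
PRMT6 (human lines) and Prmt6 (mouse) in CPM for each library, with group means and standard deviations. PRMT6 is lower in each knockdown library of both lines, and mouse Prmt6 overlaps between wildtype and the libraries labelled MMTV-PRMT6.

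The MCF-7 comparison asks which genes change when PRMT6 is lowered in a line that depends on the oestrogen receptor. The largest rises included PTPMT1, a mitochondrial phosphatase needed for cardiolipin (hg38 chromosome 11, 47565430 to 47573461), from 7.13 ± 0.879 to 21.3 ± 0.684 CPM (mean ± SD, n = 3), a log2 fold change of 1.57 (SE 0.08, adjusted p 3.5e-17), the scale of all changes here. CCND3, a D-type cyclin of the entry into the cell cycle, went from 21.4 ± 2.82 to 59.7 ± 1.26 CPM, 1.47 (SE 0.06, adjusted p 6.6e-18). DNMT3B, which sets new DNA methylation, went from 26.7 ± 0.167 to 69.7 ± 2.36 CPM, 1.39 (SE 0.05, adjusted p 5.7e-22). The kinetochore protein BOD1 rose by 1.34 (SE 0.04), the stress protein SESN3 by 1.30 (SE 0.07), the secreted decoy receptor TNFRSF11B by 1.44 (SE 0.12) and AHRR, a repressor of the aryl hydrocarbon receptor, by 1.37 (SE 0.12). The keratin KRT23 (1.54, SE 0.11), the matrix protease MMP9 (1.44, SE 0.14) and the matrix protein EMID1 (1.33, SE 0.14) also rose. In the MDA-231 controls, on which the class term rests, KRT23 had 0, 0 and 1 counts, MMP9 6, 5 and 4 and EMID1 0, 0 and 0. With that term KRT23 was at 5.21 (SE 2.43, adjusted p 0.202) and MMP9 at 1.71 (SE 0.90, adjusted p 0.283), and for EMID1 it could not be estimated. These 3 calls ended on a poorly estimated term, which decides nothing on them.

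Besides PRMT6, the largest falls were of the mitochondrial ribosomal RNAs MT-RNR1 (−7.04, SE 0.51) and MT-RNR2 (−4.51, SE 0.41), which followed the library class in both lines and have near-identical nuclear copies that make their counts uncertain. Both shrank with the class term, MT-RNR1 (from −7.04, SE 0.51, to −3.44, SE 0.72, adjusted p 0.0236) and MT-RNR2 (from −4.51, SE 0.41, to −2.51, SE 0.59, adjusted p 0.0389). HEXB, a lysosomal enzyme that degrades glycolipids (hg38 chromosome 5, 74640023 to 74722647), went from 134 ± 10.5 to 25.3 ± 0.777 CPM, −2.41 (SE 0.05, adjusted p 8.4e-24). The lipid hydrolase ABHD4 (−2.20, SE 0.09), the orphan receptors GPR160 (−2.02, SE 0.08) and GPR27 (−1.58, SE 0.08) and the carbonyl reductase CBR1 (−1.78, SE 0.05) fell too. So did ARL6IP6 (−1.58, SE 0.08) and IGFBP4, a binding protein of insulin-like growth factors that oestrogen induces, from 178 ± 13.9 to 47.5 ± 2.40 CPM, −1.91 (SE 0.05, adjusted p 1.1e-15). Among these, HEXB, ABHD4, CBR1, ARL6IP6 and IGFBP4 carry the 7-base word GTACTAC in the 3′ untranslated region (UTR), and GPR160 carries neither this word nor TGGTCCC. GPR27 had no count in the MDA-231 controls, so the class term could not be estimated for it and its lost call there decides nothing. In all, 3617 genes rose and 3721 fell of 17034 tested at an adjusted p under 0.05 (edgeR quasi-likelihood test). Of these, 189 rose and 144 fell at least 2-fold, and tested against a 1.2-fold change 1021 rose and 1006 fell. With the class term, which widens errors, 1194 rose and 792 fell. Whether the 3 libraries of a group were separate transfections is not stated, so the p-values measure the spread between these libraries only.

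Targets of the oestrogen receptor moved in both directions in MCF-7. ESR1 was at −0.11 (SE 0.03, adjusted p 0.00450), the progesterone receptor PGR at −0.25 (SE 0.04, adjusted p 2.1e-05) and the secreted protein TFF1 at −0.36 (SE 0.03, adjusted p 4.0e-11). ESR1, PGR and TFF1 were nearly unread in the MDA-231 controls (2, 4 and 2, 8, 4 and 5 and 0, 4 and 0 counts), so the class term was poorly estimated for them. With it they were at 0.04 (SE 0.86, adjusted p 1.00), 0.22 (SE 0.75, adjusted p 0.949) and −4.22 (SE 3.24, adjusted p 0.526), and the calls ended on wide errors, which decides nothing on them. The growth regulator GREB1 (−0.07, SE 0.03, adjusted p 0.0682) and the cyclin CCND1 (0.06, SE 0.03, adjusted p 0.1503) did not pass. Of 30 oestrogen receptor targets tested, 10 rose, 7 fell and 13 did not pass, and 10 rose and 7 fell adjusted over the list alone. STC2 (0.48) and PKIB (0.61) were among those that rose, and IGFBP4 and XBP1 (−0.38) among those that fell. Once the class term was in the fit, the calls of PKIB (from 0.61, SE 0.04, to 0.39, SE 0.16, adjusted p 0.156) and XBP1 (from −0.38, SE 0.03, to −0.23, SE 0.12, adjusted p 0.266) ended with smaller folds and wider errors. That of STC2 (from 0.48, SE 0.03, to −0.57, SE 0.61, adjusted p 0.740) ended on a poorly estimated term, since it had 13, 15 and 4 counts in the MDA-231 controls. The list as a whole did not move against other genes (camera adjusted p 0.991), with a mean of −0.01 and a test direction upward.

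Genes of NF-κB, the transcription factor of inflammatory signals, went both ways in MCF-7. Its subunit NFKB1 rose by 0.31 (SE 0.04, adjusted p 5.8e-07), the inhibitor NFKBIA by 0.13 (SE 0.04, adjusted p 0.00456), and the subunit RELA changed by −0.13 (SE 0.04, adjusted p 0.0161). With the class term NFKB1 was at 0.33 (SE 0.09, adjusted p 0.00831), NFKBIA at 0.18 (SE 0.09, adjusted p 0.264) and RELA at −0.17 (SE 0.10, adjusted p 0.356), so NFKBIA and RELA lost their calls with larger folds and wider errors. Of 20 NF-κB targets tested, 11 rose, 3 fell and 6 did not pass, and 12 rose and 3 fell adjusted over the list alone. TNFAIP2 (0.94) and TNFAIP3 (0.61) rose, and SOD2 (−0.54) and CCL5 (−1.10) fell against the list. The list did not pass (camera adjusted p 0.157), but it did without the low count filter (0.0114), with the class term (0.0390, over the 28 members tested in all 12 libraries) and by fry (0.00920, range over its alternatives 0.00920 to 0.677). The fits without the filter and with the class term add members with too few MCF-7 counts to pass it. Without the filter the list mean went from 0.23 to 0.48. The pathway members (9 up and 8 down of 19, 9 and 8 adjusted over the list alone, adjusted p 0.423) included a higher MAP3K7 (0.31) and a lower RIPK1 (−0.35). Under the class term the calls of RIPK1 (from −0.35, SE 0.05, to −0.29, SE 0.10, adjusted p 0.0585) and CCL5 (from −1.10, SE 0.33, to −3.22, SE 3.49, adjusted p 0.690) ended, with a smaller fold and a wider error for RIPK1 and on 1, 0 and 0 counts in the MDA-231 controls for CCL5.

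DNA replication genes rose together in MCF-7. Of 30 tested, 24 rose, 2 fell and 4 did not pass, and 24 rose and 2 fell adjusted over the list alone, with a mean of 0.30. The helicase subunit MCM2 (0.66), the thymidine kinase TK1 (0.80) and the transcription factor E2F2 (1.12) rose, and CDC6 (−0.26) and RRM2 (−0.15) fell against the list. Camera gave an adjusted p of 3.8e-12, and 0.0797 with an estimated correlation. Mitosis genes such as the kinesin KIF20A (0.38) and TOP2A (0.28) were higher as a list (18 up and 3 down of 28, 18 and 3 adjusted over the list alone, adjusted p 0.00849, 0.677 with an estimated correlation), while AURKA (−0.14), CENPE (−0.16) and CDC25C (−0.18) fell. Of 5 genes fixed in advance as reported targets of repression by PRMT6, THBS1, a matrix protein that restrains vessel growth, rose by 0.38 (SE 0.03, adjusted p 2.0e-11) and TP53 by 0.41. The cell cycle inhibitors CDKN1A (−0.19, SE 0.04, adjusted p 5.0e-05) and CDKN1B (−0.63) fell, and the list did not pass (2 up and 2 down of 5, 2 and 2 adjusted over the list alone, adjusted p 0.972). CDKN1B carries GTACTAC in its 3′ UTR, THBS1 carries TGGTCCC, and with the class term CDKN1A was at −0.28 (SE 0.11, adjusted p 0.1201), a larger fold with a wider error. With that term the calls of CDC6 (from −0.26, SE 0.04, to −0.09, SE 0.09, adjusted p 0.659), RRM2 (from −0.15, SE 0.03, to −0.09, SE 0.08, adjusted p 0.606), AURKA (from −0.14, SE 0.04, to −0.07, SE 0.08, adjusted p 0.733), CENPE (from −0.16, SE 0.04, to −0.000843, SE 0.12, adjusted p 1.00), CDC25C (from −0.18, SE 0.07, to −0.13, SE 0.12, adjusted p 0.598) and TP53 (from 0.41, SE 0.04, to 0.27, SE 0.09, adjusted p 0.0529) ended too. Their folds shrank and their errors widened.

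The other MCF-7 lists did not pass by camera with the settings chosen, and had members on either side. Targets of p53 (4 up and 11 down of 24, 5 and 11 adjusted over the list alone, adjusted p 0.237) had ZMAT3 higher (0.58) and CCNG1 lower (−0.73). Interferon genes (5 up and 11 down of 31, 5 and 11 adjusted over the list alone, adjusted p 0.237) had IFI44 higher (0.76) and ISG15 lower (−0.48). Growth factor genes linked to endocrine resistance (14 up and 8 down of 31, 14 and 8 adjusted over the list alone, adjusted p 0.157) included the receptors MET (1.12) and FGFR2 (0.82), which rose, and AKT2 (−0.56) and CDK6 (−0.45), which fell. Luminal markers (3 up and 7 down of 12, 3 and 7 adjusted over the list alone, adjusted p 0.112) had KRT18 higher (0.24) and KRT19 lower (−0.48), and this list passed without control 1 (mean −0.14, adjusted p 0.0304, range over its alternatives 0.00238 to 0.677). Basal markers (3 up and 2 down of 9, 4 and 2 adjusted over the list alone, adjusted p 0.972) had CAV1 higher (0.51) and CAV2 lower (−0.86), with a mean of 0.17 and a median of −0.03. Mesenchymal genes (5 up and 3 down of 17, 7 and 3 adjusted over the list alone, adjusted p 0.409) had SERPINE1 higher (0.61) and COL1A1 lower (−0.92). Epithelial junction genes (8 up and 8 down of 22, 10 and 9 adjusted over the list alone, adjusted p 0.441) had CDH3 higher (0.31) and ESRP1 lower (−0.57), with a mean of −0.04 and a median of 0.03. FGFR2 (from 0.82, SE 0.05, to 0.29, SE 1.72, adjusted p 1.00), CDH3 (from 0.31, SE 0.04, to 0.25, SE 1.15, adjusted p 0.983) and ESRP1 (from −0.57, SE 0.03, to −0.32, SE 0.48, adjusted p 0.805) lost their calls with the class term. They had 2, 3 and 1, 1, 6 and 2 and 10, 21 and 11 counts in the MDA-231 controls, so that term was poorly estimated for them.

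Of the metabolic lists in MCF-7, genes of the unfolded protein response (9 up and 7 down of 26, 9 and 7 adjusted over the list alone, adjusted p 0.237) included PDIA4, a chaperone of the endoplasmic reticulum, which rose by 1.28, and SLC7A11, which was at −0.53. Their mean was 0.04 and their median −0.05. Cholesterol synthesis genes (5 up and 7 down of 23, 5 and 7 adjusted over the list alone, adjusted p 0.310) had FDPS higher (0.23) and SC5D lower (−1.01). Hypoxia genes (6 up and 2 down of 23, 6 and 2 adjusted over the list alone, adjusted p 0.972) had EGLN3 higher (0.49) and NDRG1 lower (−0.79). The hypoxia mean was −0.02 with an upward test direction, and AKT2, SC5D, NDRG1 and SLC7A11 carry GTACTAC in the 3′ UTR. Oxidative phosphorylation genes (8 up and 15 down of 34, 8 and 15 adjusted over the list alone, adjusted p 0.351) had COX6C higher (0.25) and UQCRB lower (−0.31). Ribosomal protein genes (10 up and 2 down of 35, 10 and 2 adjusted over the list alone, adjusted p 0.237), whose many processed copies make their counts uncertain, had RPS15 higher (0.24) and RPS6 lower (−0.21). Of the other arginine methyltransferases (2 up and 4 down of 7, 2 and 4 adjusted over the list alone, adjusted p 0.241), PRMT2 rose (0.33) and PRMT3 (−0.89), PRMT5 (−0.28) and PRMT1 (−0.16) fell, and PRMT3 carries GTACTAC. Once the class term was in the fit, the calls of UQCRB (from −0.31, SE 0.03, to −0.13, SE 0.08, adjusted p 0.349), RPS15 (from 0.24, SE 0.04, to 0.21, SE 0.09, adjusted p 0.169), RPS6 (from −0.21, SE 0.03, to −0.07, SE 0.09, adjusted p 0.733) and PRMT1 (from −0.16, SE 0.04, to −0.17, SE 0.09, adjusted p 0.250) ended with wider errors, and the folds of UQCRB, RPS15 and RPS6 were smaller.

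Some of these MCF-7 lists passed under an alternative. Interferon genes such as ISG15 passed without the low count filter (mean −0.34, adjusted p 0.0148) and in the fit of all 12 human libraries (mean −0.33, adjusted p 0.0332, range over its alternatives 0.0148 to 0.807). Growth factor genes such as MET passed without the filter (mean 0.20, adjusted p 0.0164, range over its alternatives 0.00238 to 0.677). Ribosomal protein genes such as RPS15 passed without the filter (mean 0.07, adjusted p 0.0148) and with the class term (mean 0.12, adjusted p 0.0408, range over its alternatives 0.0148 to 0.788). Luminal markers such as KRT19 passed without the filter (mean −0.13, adjusted p 0.0114) and by DESeq2 (mean −0.13, adjusted p 0.0220). By fry, which asks whether members change at all rather than more than other genes, the p53, mesenchymal, epithelial junction, unfolded protein, cholesterol, methyltransferase, growth factor, NF-κB pathway and luminal lists passed (adjusted p 0.00238 to 0.0366).

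Some MCF-7 genes named above did not pass in each fit with a library left out. In the weakest such fit of each gene, RELA (from −0.13, SE 0.04, to −0.11, SE 0.05, adjusted p 0.0975), NFKBIA (from 0.13, SE 0.04, to 0.10, SE 0.04, adjusted p 0.05004), CCL5 (from −1.10, SE 0.33, to −0.69, SE 0.36, adjusted p 0.140) and CDC25C (from −0.18, SE 0.07, to −0.14, SE 0.07, adjusted p 0.136) lost their calls with smaller folds.

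The MDA-231 comparison asks the same of a line in which ESR1 was nearly unread (2 to 4 counts per library), as were PGR (1 to 8) and TFF1 (0 to 10), so none of these was tested. The largest rise was of IL11, a cytokine of tumour and bone signalling (hg38 chromosome 19, 55364389 to 55370463), from 14.7 ± 0.399 to 79.1 ± 6.32 CPM (mean ± SD, n = 3), 2.44 (SE 0.07, adjusted p 1.4e-15). SERPINB9, which blocks granzyme B, went from 7.25 ± 0.293 to 37.5 ± 1.22 CPM, 2.36 (SE 0.09, adjusted p 2.4e-14). ACLY, which makes acetyl-CoA for lipid synthesis, went from 180.4 ± 6.82 to 674 ± 3.92 CPM, 1.90 (SE 0.05, adjusted p 2.4e-16), and CCNE2, a cyclin of DNA replication, from 6.34 ± 1.38 to 22.5 ± 2.23 CPM, 1.80 (SE 0.12, adjusted p 2.8e-10). The membrane proteins TMEM64 (2.34, SE 0.07) and TMEM87B (2.24, SE 0.07), the lipid scramblase PLSCR4 (2.23, SE 0.12) and the xenobiotic enzyme CYP1A1 (1.94, SE 0.14) rose. So did the sugar transferase GXYLT1 (1.70, SE 0.07) and the ubiquitin ligase adaptor KLHL15 (1.70, SE 0.07).

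The largest fall in MDA-231 was of PPM1E, a phosphatase that acts on kinases such as AMPK (hg38 chromosome 17, 58755869 to 58985176), from 8.61 ± 0.755 to 2.06 ± 0.875 CPM, −2.02 (SE 0.19, adjusted p 4.1e-08). PRMT6 came next, then C6orf120 (−1.75, SE 0.09), the receptor GPR160 (−1.72, SE 0.11), the reductase CBR1 (−1.65, SE 0.07) and the matrix protein MATN3 (−1.64, SE 0.16). The actin-binding CNN2 went from 84.5 ± 0.983 to 28.0 ± 1.78 CPM, −1.60 (SE 0.06, adjusted p 1.3e-13). PCBD1 (−1.52, SE 0.11), GPD1L (−1.51, SE 0.07) and the mitochondrial import protein TOMM40L (−1.43, SE 0.09) fell as well. PPM1E, C6orf120, CBR1, MATN3 and GPD1L carry GTACTAC in the 3′ UTR, PPM1E and TOMM40L carry TGGTCCC, and GPR160, CNN2 and PCBD1 carry neither. In all, 2853 genes rose and 2794 fell of 16418 tested (edgeR). Of these, 194 rose and 116 fell at least 2-fold, and tested against a 1.2-fold change 1069 rose and 848 fell.

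The cell cycle inhibitor CDKN1A rose in MDA-231, by 0.65 (SE 0.08, adjusted p 8.4e-07), as did THBS1, by 0.79 (SE 0.05, adjusted p 2.3e-10), and CCND1, by 0.19 (SE 0.05, adjusted p 0.00311). NFKB1 was at −0.24 (SE 0.05, adjusted p 5.7e-04). Against control 3 alone, a single library assumed to vary like the knockdown group, CCND1 was at 0.23 (SE 0.09, adjusted p 0.0928) and NFKB1 at −0.23 (SE 0.09, adjusted p 0.0847). With fewer libraries the folds were close to these and the errors wider. RELA (−0.10, SE 0.06, adjusted p 0.224), NFKBIA (−0.11, SE 0.06, adjusted p 0.204) and GREB1 (0.13, SE 0.26, adjusted p 0.749) did not pass. Of 26 NF-κB targets tested, 7 rose, 7 fell and 12 did not pass, and 7 rose and 7 fell adjusted over the list alone. The adhesion molecule ICAM1 (0.73) and IER3 (0.70) rose while the chemokine CXCL1 (−0.59) fell, and the list did not pass (camera adjusted p 0.685, mean 0.04, median −0.06). Of 18 oestrogen receptor targets tested, 6 rose, 4 fell and 8 did not pass, and 6 rose and 5 fell adjusted over the list alone, with CA12 higher (0.79) and NRIP1 lower (−0.70), which carries GTACTAC. That list did not pass (camera adjusted p 0.946), with a mean of 0.08 and a test direction downward. Genes reported as repressed by PRMT6 (2 up and 2 down of 4, 2 and 2 adjusted over the list alone, adjusted p 0.649) had CDKN1B (−0.90) and TP53 (−0.22) lower beside the higher THBS1 and CDKN1A. By fry this list passed upward (0.0486, range over its alternatives 0.0486 to 0.816), with a mean of 0.08. Pathway members of NF-κB (2 up and 4 down of 19, 2 and 4 adjusted over the list alone, adjusted p 0.649) had CHUK higher (0.33) and REL lower (−0.32). The calls of TP53 (from −0.22, SE 0.06, to −0.10, SE 0.08, adjusted p 0.454) and REL (from −0.32, SE 0.09, to −0.30, SE 0.12, adjusted p 0.0838) ended with the class term, with smaller folds and wider errors.

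DNA replication genes rose together in MDA-231 too. Of 30 tested, 27 rose, 1 fell and 2 did not pass, and 27 rose and 1 fell adjusted over the list alone, with a mean of 0.63. E2F1 (1.32), CCNE2 and MCM2 (0.82) rose and CCNE1 (−0.44) fell against the list. Camera gave an adjusted p of 7.6e-32, and 0.164 with an estimated correlation. Mitosis genes such as CENPA (0.67) and CDK1 (0.43) rose (16 up and 1 down of 28, 19 and 2 adjusted over the list alone, adjusted p 5.6e-04, 0.322 with an estimated correlation), CDC20 (−0.15) against them. Mesenchymal genes rose (12 up and 4 down of 22, 14 and 4 adjusted over the list alone, adjusted p 0.00285, 0.189 with an estimated correlation), with SERPINE1 (0.71) and TGFBI (0.65) higher, and COL4A1 (−0.68), COL1A1 (−1.39), VIM (−0.22) and ACTA2 (−0.38) lower. Hypoxia genes rose (11 up and 0 down of 24, 11 and 0 adjusted over the list alone, adjusted p 0.00285, 0.322 with an estimated correlation), led by the vessel growth factor VEGFA (1.15) and ADM (0.55). Cholesterol synthesis genes rose (14 up and 3 down of 24, 16 and 4 adjusted over the list alone, adjusted p 0.00285, 0.415 with an estimated correlation), with PCSK9 (0.62) and HMGCS1 (0.39) higher and SC5D (−0.39), LSS (−0.24) and TM7SF2 (−0.34) lower. Under the class term the calls of CDC20 (from −0.15, SE 0.05, to −0.08, SE 0.07, adjusted p 0.512) and TM7SF2 (from −0.34, SE 0.11, to −0.23, SE 0.15, adjusted p 0.342) ended with smaller folds and wider errors.

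Epithelial junction genes fell in MDA-231 (0 up and 6 down of 16, 0 and 6 adjusted over the list alone, adjusted p 0.0106, 0.284 with an estimated correlation), among them the keratin KRT19 (−0.95) and the desmosome protein DSP (−0.43). Fitted with the class term, over the 22 members tested in all 12 libraries, some nearly unread in MDA-231, this call was lost (mean 0.01, adjusted p 0.0596, range over its alternatives 0.00129 to 0.284). The other arginine methyltransferases fell (0 up and 4 down of 7, 0 and 4 adjusted over the list alone, adjusted p 0.00698, 0.284 with an estimated correlation), namely PRMT3 (−0.69), PRMT5 (−0.49), PRMT1 (−0.36) and CARM1 (−0.17). The call of CARM1 ended with the class term (from −0.17, SE 0.05, to −0.13, SE 0.07, adjusted p 0.252), with a smaller fold and a wider error. Luminal markers fell (0 up and 2 down of 8, 0 and 2 adjusted over the list alone, adjusted p 0.0382, 0.293 with an estimated correlation) with KRT19 and AGR2 (−0.97), a call that was lost without knockdown library 1 (mean −0.19, adjusted p 0.0769), by limma-voom (0.152) and with protein-coding genes alone (0.0660). It was also lost over the 12 members tested in all 12 human libraries, in the fit with the groups alone (mean 0.14, adjusted p 0.175) and with the class term (0.37, 0.178, range over its alternatives 0.00577 to 0.293).

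The remaining MDA-231 lists did not pass by camera with the settings chosen. Targets of p53 (5 up and 4 down of 22, 5 and 4 adjusted over the list alone, adjusted p 0.926) had RRM2B higher (0.65) and CCNG1 lower (−0.72), with a mean of 0.04 and a median of −0.01. Interferon genes (9 up and 2 down of 28, 10 and 3 adjusted over the list alone, adjusted p 0.685) had IFIT2, whose close relatives make its count uncertain, higher (0.54) and BST2 lower (−0.70). Growth factor genes (9 up and 8 down of 29, 11 and 10 adjusted over the list alone, adjusted p 0.578) had the kinases CDK6 (1.06) and AKT3 (0.67) higher and MYC (−0.39) and IGF1R (−0.52) lower. Genes of the unfolded protein response (11 up and 3 down of 26, 11 and 3 adjusted over the list alone, adjusted p 0.181), with PSAT1 higher (0.47) and HERPUD1 lower (−0.33), passed without the low count filter (mean 0.09, adjusted p 0.0400) and without knockdown library 1 (mean 0.15, adjusted p 0.0120, range over its alternatives 0.0120 to 0.934). Ribosomal protein genes (0 up and 4 down of 35, 0 and 0 adjusted over the list alone, adjusted p 0.650), such as RPS23 (−0.17), passed without knockdown library 3 (mean −0.10, adjusted p 0.0251, range over its alternatives 0.0251 to 0.984). Oxidative phosphorylation genes (1 up and 5 down of 34, 1 and 4 adjusted over the list alone, adjusted p 0.718) had COX6A1 lower (−0.69) and COX8A higher (0.21). Basal markers (4 up and 4 down of 12, 4 and 5 adjusted over the list alone, adjusted p 0.829) had PLAU higher (0.45) and CD44 lower (−0.25). The basal mean was 0.05 and the median −0.03. The oxidative phosphorylation mean was −0.02, with a median just above 0.

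The same was so for some MDA-231 genes with a library left out. In the weakest such fit of each gene, the calls of CCNE1 (from −0.44, SE 0.15, to −0.36, SE 0.17, adjusted p 0.137), CDC20 (from −0.15, SE 0.05, to −0.09, SE 0.05, adjusted p 0.270), TP53 (from −0.22, SE 0.06, to −0.18, SE 0.07, adjusted p 0.0671), ACTA2 (from −0.38, SE 0.12, to −0.34, SE 0.14, adjusted p 0.0859) and TM7SF2 (from −0.34, SE 0.11, to −0.25, SE 0.13, adjusted p 0.159) ended. So did those of COX8A (from 0.21, SE 0.06, to 0.19, SE 0.07, adjusted p 0.0574), RPS23 (from −0.17, SE 0.05, to −0.15, SE 0.06, adjusted p 0.0721), CARM1 (from −0.17, SE 0.05, to −0.12, SE 0.06, adjusted p 0.141) and REL (from −0.32, SE 0.09, to −0.24, SE 0.10, adjusted p 0.0762). Each fold was smaller there.

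**Figure D3:**
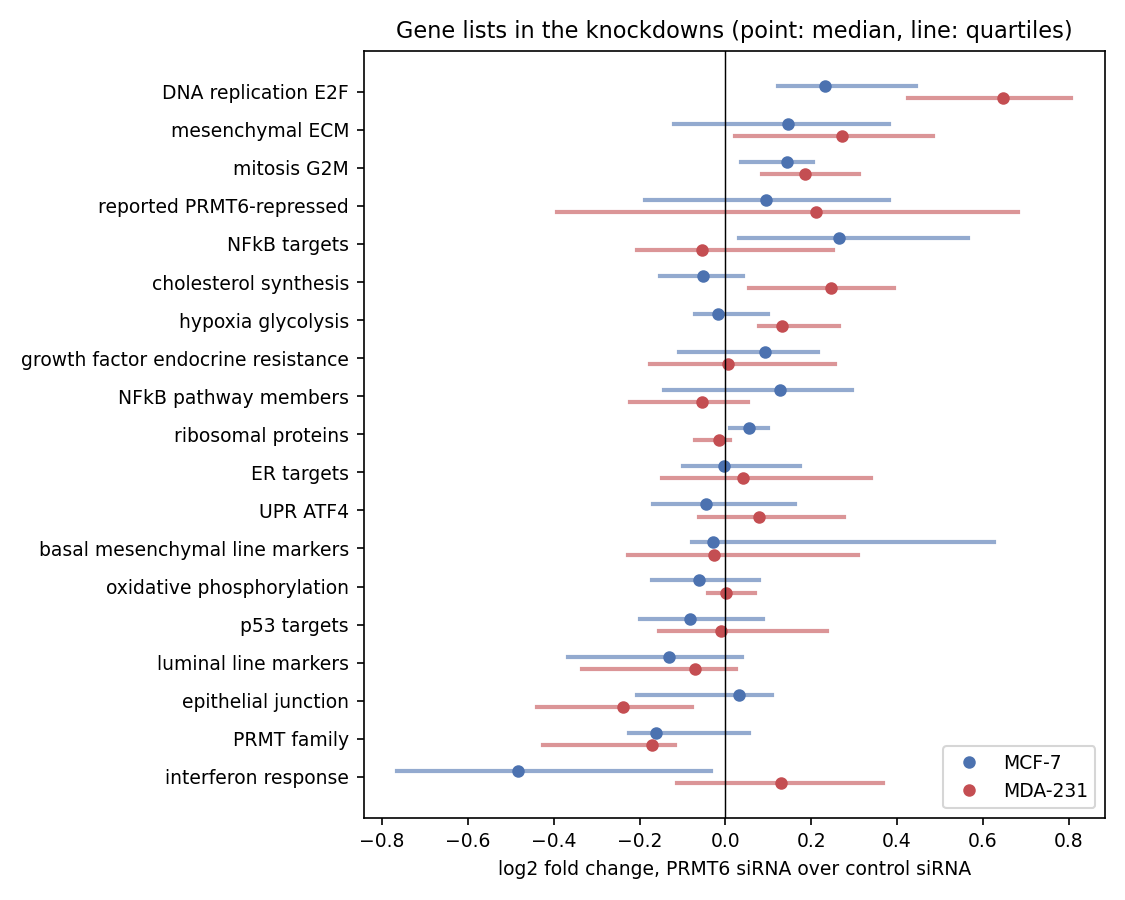
Log2 fold changes of the list members in MCF-7 and MDA-231, PRMT6 siRNA against control siRNA, as the median and the quartiles of each gene list. NF-κB targets and DNA replication have the highest medians in MCF-7, and DNA replication has the highest in MDA-231.

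Both lines were compared to ask which genes answer to the PRMT6 siRNA regardless of ESR1. Shared rises, given for MCF-7 and then MDA-231, included the helicase subunits MCM2 (0.66 and 0.82), MCM3 (0.54 and 0.65) and MCM6 (0.61 and 0.65), the zinc finger ZNF367 (0.64 and 1.49), WDR76 (0.83 and 1.39) and SBNO1 (0.74 and 0.53). The stress protein SESN3 (1.30 and 0.72), the arrestin ARRDC3 (0.64 and 0.82), the transglutaminase TGM2 (0.89 and 0.75) and the GTPase NRAS (0.79 and 0.57) rose as well. HEXB was among the shared falls, at −2.41 (SE 0.05) in MCF-7 and −1.41 (SE 0.06) in MDA-231. PARK7, a guard against oxidative stress (−1.19 and −1.32), CBR1 (−1.78 and −1.65), the purine enzyme PAICS (−1.13 and −1.10), GPD1L (−1.52 and −1.51), CNN2 (−1.23 and −1.60), the proton pump subunit ATP6AP1 (−1.48 and −1.31), BCAP31 (−1.43 and −1.33), the translation factor EIF4G2 (−0.93 and −1.16) and CHP1 (−1.29 and −1.07) fell too. HEXB, CBR1, PAICS, GPD1L, ATP6AP1 and CHP1 carry GTACTAC in the 3′ UTR, BCAP31 and EIF4G2 carry TGGTCCC, and PARK7 and CNN2 carry neither. Among 14225 genes tested in both, 1084 rose in both (577 from independent lists) and 1266 fell in both (623 from independent lists). Opposite calls numbered 295 and 366. The lines have separate controls, and genes are not independent replicates. With the class term 788 genes were called in the same direction against 195 from independent lists.

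**Figure D4:**
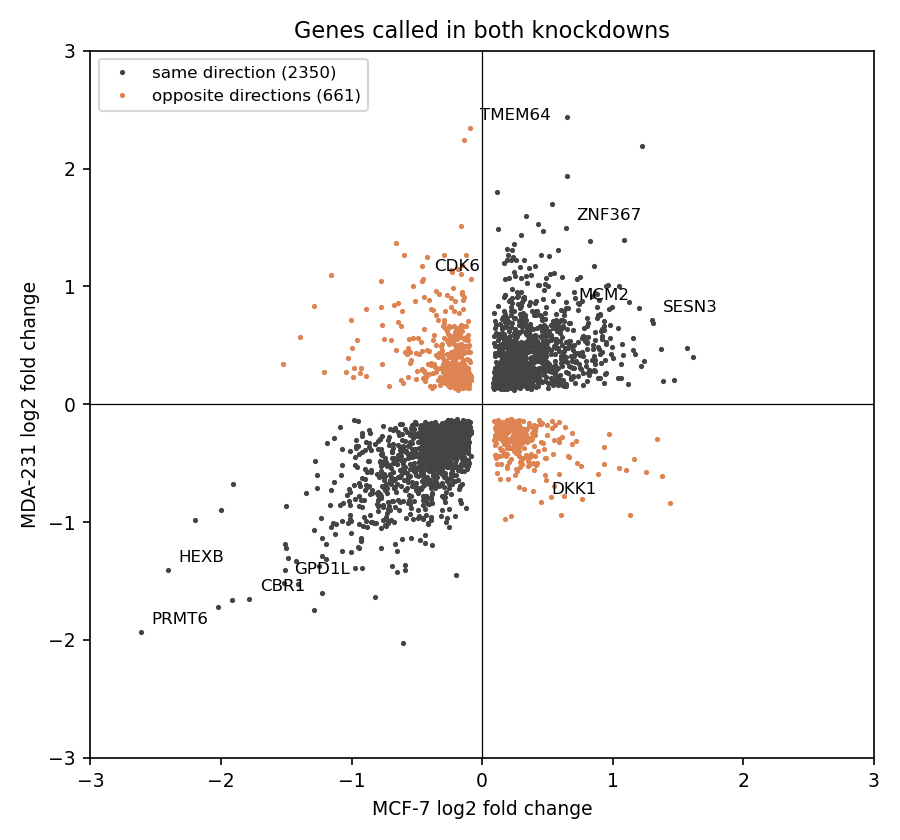
Log2 fold change in MCF-7 (x axis) against MDA-231 (y axis) for the 3011 genes called in both lines, of which 3 lie outside the axes. In 2350 of these genes the directions match, and in 661 they are opposite.

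Whether the siRNA effect differs between the lines was tested as an interaction over the 12 human libraries, with differences given as MCF-7 minus MDA-231. CDKN1A differed by −0.79 (SE 0.08, adjusted p 6.1e-10), NFKB1 by 0.60 (SE 0.07, adjusted p 6.6e-09), NFKBIA by 0.28 (SE 0.07, adjusted p 0.00326) and THBS1 by −0.36 (SE 0.06, adjusted p 2.8e-05). The fall of PRMT6 was larger in MCF-7, by −0.63 (SE 0.12, adjusted p 1.4e-04). With the class term CDKN1A was at −1.03 (SE 0.20, adjusted p 9.0e-04), NFKB1 at 0.56 (SE 0.14, adjusted p 0.0124), NFKBIA at 0.30 (SE 0.16, adjusted p 0.369), THBS1 at −0.28 (SE 0.13, adjusted p 0.304) and PRMT6 at −0.73 (SE 0.23, adjusted p 0.0667). The NFKBIA, THBS1 and PRMT6 calls ended with wider errors, the fold larger for NFKBIA and PRMT6 and smaller for THBS1. RELA (0.02, SE 0.08, adjusted p 0.913), CCND1 (−0.09, SE 0.06, adjusted p 0.319) and GREB1 (−0.15, SE 0.21, adjusted p 0.702) were not detectably different. In all, the effect differed for 4434 of 19599 genes (edgeR), 2665 with the more positive effect in MCF-7 and 1769 in MDA-231, and in 2744 of them the fitted directions were opposite. With the class term, which widens errors, it differed for 722 genes.

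The 10 largest differences were mostly of genes read in one line and near the floor in the other, so no fold is given for those genes. The morphogen BMP7 had 6613 to 10530 counts per library in MCF-7 and 0 to 2 in MDA-231, and the kinase scaffold KSR2 126 to 206 and 0 to 7. The transporter SLC4A10 had 237 to 342 and 0 to 2, CRLF1 157 to 467 and 0 to 3, and IGSF9 203 to 569 and 0 to 4. The transcription factor ETS1 had 0 to 6 in MCF-7 and 6144 to 15965 in MDA-231, PELI2 0 to 5 and 252 to 408, and the actin-binding NEXN 0 to 8 and 202 to 551. MT-RNR1 differed by −9.41 (SE 1.51, adjusted p 0.00202) and MT-RNR2 by −6.10 (SE 0.85, adjusted p 8.9e-04), both in the direction of the library class. Both calls ended with the class term as the differences shrank (MT-RNR1 from −9.41, SE 1.51, to −4.49, SE 1.18, adjusted p 0.107, and MT-RNR2 from −6.10, SE 0.85, to −3.17, SE 0.97, adjusted p 0.166). The calls of BMP7, KSR2, SLC4A10, CRLF1, IGSF9, ETS1 and PELI2 ended too (adjusted p 0.122 to 1.00), the first 5 on a term poorly estimated for genes near the floor in MDA-231. For ETS1 and PELI2 the SE hardly changed (from 1.45 to 1.49 and from 1.35 to 1.39), and why their calls ended was not tested.

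The mouse comparison asks what differs in mammary cells labelled MMTV-PRMT6 against wildtype. Milk and secretory genes were far lower. The milk protein Wap went from 134570.0 ± 25148 to 909 ± 1054 CPM (mean ± SD, n = 3), −7.21 (SE 1.05, adjusted p 6.2e-04), the casein Csn1s2b from 108780.0 ± 31455 to 400.3 ± 531 CPM, −8.09 (SE 1.27, adjusted p 9.0e-04), and the casein Csn2 from 113660.0 ± 26455 to 1457 ± 956 CPM, −6.29 (SE 0.74, adjusted p 2.3e-04). Library 3 carried most of the remainder, at 293, 308 and 2126 CPM of Wap and 106, 81.8 and 1013 CPM of Csn1s2b in MMTV-PRMT6 libraries 1, 2 and 3. Without it Wap was at −8.81 (SE 0.54, adjusted p 1.0e-04) and Csn1s2b at −10.18 (SE 0.63, adjusted p 1.0e-04). Pigr, which carries antibodies into milk, went from 5989 ± 1587 to 49.1 ± 28.6 CPM, −6.94 (SE 0.52, adjusted p 4.5e-05), and Ccl28, a chemokine that draws antibody-secreting cells, was at −7.39 (SE 0.97). The secreted proteins Prol1 (−10.19, SE 1.18) and Pip (−8.43, SE 0.58), the protease inhibitor Serpinb11 (−8.24, SE 0.83), the gasdermins Gsdma (−7.32, SE 0.67) and Gsdmc (−6.90, SE 0.55), whose counts are uncertain since they have near-identical relatives, and the transporter Slc22a1 (−6.95, SE 0.77) fell. The milk list took 45.9% ± 4.22 (SD, n = 3) of gene counts in wildtype and 0.811, 1.48 and 2.74% in MMTV-PRMT6 libraries 1, 2 and 3.

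Among rises, Foxi1 (6.16, SE 0.73), a transcription factor of proton-secreting cells, stood with the proton pump subunits Atp6v1b1, from 0.310 ± 0.118 to 61.0 ± 20.2 CPM, 7.56 (SE 0.40, adjusted p 1.8e-05), and Atp6v0d2 (5.05, SE 0.45). The bone and milk glycoprotein Spp1 went from 11.1 ± 8.19 to 891 ± 155 CPM, 6.30 (SE 0.56, adjusted p 8.3e-05), and the mucus protein Fcgbp from 1.45 ± 0.876 to 328 ± 33.8 CPM, 7.71 (SE 0.31, adjusted p 1.1e-05). Nnat (8.17, SE 0.72), the iron reductase Cybrd1 (6.57, SE 0.71), the fibrinogen chain Fgb (5.62, SE 0.43) and the choline transporter Slc5a7 (5.62, SE 0.41) rose. Cybrd1 was near the floor in wildtype, at 0, 0.201 and 0 CPM in libraries 1, 2 and 3. Gabrp, a GABA receptor subunit, had no count in wildtype and 7.62 ± 2.75 CPM in the libraries labelled MMTV-PRMT6, at least 71.8-fold higher than the floor of 3 counts over the wildtype group (0.106 CPM). Such floors and intervals cover counting error only. With a library left out the folds of some mouse genes ranged widely while all of them passed: Nnat 7.48 to 8.97, Cybrd1 5.87 to 10.32, Foxi1 5.54 to 8.28, Spp1 5.88 to 7.10, Fgb 5.21 to 6.30, Atp6v0d2 4.64 to 5.68, Prol1 −10.70 to −9.52, Pip −9.31 to −7.96, Serpinb11 −8.66 to −7.60, Ccl28 −8.72 to −6.85 and Gsdmc −7.49 to −6.30. In all, 4971 genes rose and 4800 fell of 14705 tested (edgeR), 3169 and 1861 of them at least 2-fold. The stage of the wildtype mice is not stated, so in these counts a difference of stage cannot be told apart from an effect of the construct. Of unique alignments, 54.7% ± 1.29 lay outside annotated genes in the libraries labelled MMTV-PRMT6 against 25.2% ± 2.50 in wildtype.

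Of the genes fixed in advance, the D-type cyclin Ccnd1 (1.07, SE 0.27, adjusted p 0.00871) and the NF-κB subunit Nfkb1 (0.57, SE 0.12, adjusted p 0.00404) were higher in the libraries labelled MMTV-PRMT6. Thbs1 (−2.45, SE 0.34, adjusted p 5.4e-04), Cdkn1a (−1.52, SE 0.26, adjusted p 0.00131), the inhibitor Nfkbia (−0.74, SE 0.18, adjusted p 0.00825) and the luminal keratin Krt18 (−1.18, SE 0.17, adjusted p 5.2e-04) were lower. Esr1 was at −0.63 (SE 0.24) with an adjusted p of 0.04996 at the threshold and overlapping groups. Pgr (0.05, SE 0.58, adjusted p 0.941), Greb1 (−1.08, SE 0.72, adjusted p 0.212) and Rela (−0.24, SE 0.11, adjusted p 0.0930) did not pass. Of 23 oestrogen receptor targets tested, 8 rose, 10 fell and 5 did not pass, and 9 rose and 10 fell adjusted over the list alone. Cxcl12 (1.62) and Igfbp4 (1.73) rose, Slc7a5 (−4.54) and Xbp1 (−2.42) fell, and the list did not pass (camera adjusted p 0.418, mean −0.37, median 0.05), though fry gave 0.0141 (range over its alternatives 0.0141 to 0.771). Of 26 NF-κB targets tested, 14 rose, 6 fell and 6 did not pass, and 14 rose and 6 fell adjusted over the list alone, with Tnfaip3 (1.61) and Ltb (2.10) higher and the chemokines Cxcl1 (−5.41) and Cxcl2 (−4.59) lower. This list did not pass (camera adjusted p 0.0788), but it passed without MMTV-PRMT6 library 2 (0.0355, mean 0.23) and by fry (0.0240, range over its alternatives 0.0240 to 0.689).

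Lists of tissue and cell types moved together in the mouse. Milk secretion genes fell (0 up and 19 down of 19, 0 and 19 adjusted over the list alone, adjusted p 6.4e-12, 0.688 with an estimated correlation), among them the milk peroxidase Lpo (−6.50) and Xdh (−4.10). Epithelial junction genes fell (2 up and 18 down of 22, 2 and 18 adjusted over the list alone, adjusted p 3.5e-08, 0.688 with an estimated correlation), such as St14 (−2.67) and Epcam (−2.43), with Dsp (1.18) and Pkp3 (0.87) against them. Fibroblast genes rose (19 up and 0 down of 19, 19 and 0 adjusted over the list alone, adjusted p 7.9e-07, 0.688 with an estimated correlation), with the matrix proteins Dcn (1.95) and Col6a1 (1.63). T cell genes rose (16 up and 0 down of 16, 16 and 0 adjusted over the list alone, adjusted p 7.1e-08, 0.688 with an estimated correlation), with Lck (2.32) and Cd5 (2.34). B and plasma cell genes rose (12 up and 2 down of 16, 12 and 2 adjusted over the list alone, adjusted p 2.9e-04, 0.688 with an estimated correlation), with Pax5 (3.34) and Ms4a1 (2.55), while the plasma cell genes Derl3 (−0.72) and Igj (−0.46) fell. Macrophage genes rose (12 up and 0 down of 15, 13 and 1 adjusted over the list alone, adjusted p 0.00248, 0.688 with an estimated correlation), with Trem2 (3.71) and Lyz2 (1.90). Mesenchymal genes rose (22 up and 3 down of 28, 22 and 3 adjusted over the list alone, adjusted p 2.9e-04, 0.688 with an estimated correlation), with Mmp2 (2.74) higher and Tagln (−1.32), Thbs1 and Acta2 (−0.86) lower.

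Lists of metabolism and proliferation moved as well. Oxidative phosphorylation genes fell (0 up and 33 down of 34, 0 and 33 adjusted over the list alone, adjusted p 1.3e-07, 0.688 with an estimated correlation), such as Ndufa1 (−1.96). Cholesterol synthesis genes fell (0 up and 21 down of 23, 0 and 22 adjusted over the list alone, adjusted p 4.1e-07, 0.688 with an estimated correlation), such as Fdps (−3.08). Genes of fatty acid synthesis fell (0 up and 13 down of 21, 0 and 13 adjusted over the list alone, adjusted p 0.00255, 0.688 with an estimated correlation), such as Elovl5 (−3.65). Genes of the unfolded protein response fell (1 up and 19 down of 26, 1 and 19 adjusted over the list alone, adjusted p 1.8e-04, 0.688 with an estimated correlation), such as Asns (−2.98), with Herpud1 (0.71) against them. Mitosis genes rose (23 up and 0 down of 28, 26 and 0 adjusted over the list alone, adjusted p 1.4e-04, 0.688 with an estimated correlation), such as Kif23 (1.79). DNA replication genes rose (17 up and 0 down of 30, 17 and 0 adjusted over the list alone, adjusted p 0.0138, 0.689 with an estimated correlation), such as Mcm2 (1.06). Hypoxia and glycolysis genes fell (6 up and 12 down of 21, 7 and 12 adjusted over the list alone, adjusted p 0.0158, 0.688 with an estimated correlation), with Slc2a1 lower (−2.80) and Pfkfb4 higher (1.12). Interferon genes fell (3 up and 13 down of 27, 3 and 13 adjusted over the list alone, adjusted p 0.0411, 0.705 with an estimated correlation), with Rsad2 lower (−2.24) and Epsti1 (1.58), Ifitm1 (1.28) and Ddx60 (0.68) higher. The interferon call was lost without wildtype library 3 (mean −0.31, adjusted p 0.188), by DESeq2 (0.0570) and with the milk genes left out (0.0503, range over its alternatives 0.0135 to 0.705), and the hypoxia call by limma-voom (0.0751, range over its alternatives 0.00254 to 0.688).

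The other mouse lists did not pass by camera with the settings chosen. Adipocyte genes (11 up and 3 down of 20, 11 and 3 adjusted over the list alone, adjusted p 0.0734) had Adipoq higher (1.69) and Cd36 lower (−1.10), and passed without wildtype library 1 (mean 0.68, adjusted p 0.0232) or MMTV-PRMT6 library 1 (0.77, 0.00372, range over its alternatives 0.00372 to 0.705). Endothelium genes (8 up and 0 down of 14, 7 and 0 adjusted over the list alone, adjusted p 0.0661), such as Cd34 (2.11), passed without wildtype library 3 (0.75, 0.0227) or MMTV-PRMT6 library 3 (0.69, 0.0412, range over its alternatives 0.0164 to 0.689). Neutrophil genes (5 up and 1 down of 8, 5 and 1 adjusted over the list alone, adjusted p 0.181), with Cxcr2 higher (2.19) and S100a8 lower (−2.06), passed without MMTV-PRMT6 library 3 (2.44, 0.00285, range over its alternatives 0.00285 to 0.705). Targets of p53 (4 up and 14 down of 22, 4 and 14 adjusted over the list alone, adjusted p 0.0654), with Ccng1 lower (−1.99) and Sesn1 higher (1.65), passed without wildtype library 1 (−0.62, 0.0180) or 2 (−0.68, 0.0227, range over its alternatives 0.00569 to 0.688). Luminal epithelium genes (7 up and 10 down of 19, 7 and 10 adjusted over the list alone, adjusted p 0.1595) had Kit higher (4.15) and Ehf lower (−3.75). Basal genes (2 up and 6 down of 15, 2 and 6 adjusted over the list alone, adjusted p 0.236) had Trp63 higher (1.14) and Myh11 lower (−1.25).

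Acute phase and involution genes (6 up and 9 down of 22, 6 and 9 adjusted over the list alone, adjusted p 0.570) had Hp (4.53) and Igfbp5 (4.60) higher and Lbp (−3.02) and Stat3 (−1.11) lower. Growth factor genes (10 up and 12 down of 31, 10 and 12 adjusted over the list alone, adjusted p 0.427) had Bcl2 (2.62) higher and Erbb3 (−1.65) lower, with a mean of 0.20 and a median of −0.04. Pathway members of NF-κB (6 up and 7 down of 19, 6 and 7 adjusted over the list alone, adjusted p 0.427) had Rel higher (1.37) and Chuk lower (−1.40). Genes reported as repressed by PRMT6 (2 up and 2 down of 4, 2 and 2 adjusted over the list alone, adjusted p 0.699) had Cdkn1b higher (0.88) beside the lower Thbs1 and Cdkn1a. Arginine methyltransferases (3 up and 2 down of 7, 3 and 3 adjusted over the list alone, adjusted p 0.944) had Prmt3 higher (0.50) and Prmt7 lower (−0.46), with a mean just above 0 and a median just below it. Ribosomal protein genes (1 up and 12 down of 34, 1 and 12 adjusted over the list alone, adjusted p 0.334) had Rpl14 lower (−0.71) and Rpl3 higher (0.60). Of skeletal muscle genes (0 up and 1 down of 14, 0 and 1 adjusted over the list alone, adjusted p 0.651) Mb was lower (−1.21), and of skin genes (0 up and 2 down of 3, 0 and 2 adjusted over the list alone, adjusted p 0.553) Krt10 (−1.36).

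Further alternatives passed some of these mouse lists. Without the low count filter p53 targets such as Ccng1 (mean −0.62, adjusted p 0.0231), adipocyte genes such as Adipoq (mean 0.59, adjusted p 0.0398) and endothelium genes such as Cd34 (mean 0.66, adjusted p 0.0368) passed, and by limma-voom the endothelium genes (mean 0.65, adjusted p 0.0285). By fry the p53, ribosomal protein, growth factor, luminal epithelium, basal, endothelium and skin lists passed (adjusted p 0.00569 to 0.0479), and the interferon list did not (0.05001).

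Leaving a library out ended some calls of single mouse genes. In the weakest such fit of each gene, Esr1 (from −0.63, SE 0.24, to −0.33, SE 0.18, adjusted p 0.153), Ddx60 (from 0.68, SE 0.21, to 0.58, SE 0.23, adjusted p 0.0689), Rpl3 (from 0.60, SE 0.20, to 0.53, SE 0.23, adjusted p 0.0876), Igj (from −0.46, SE 0.15, to −0.40, SE 0.18, adjusted p 0.0884) and Krt10 (from −1.36, SE 0.39, to −0.77, SE 0.31, adjusted p 0.0658) no longer passed, each with a smaller fold.

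**Figure D5:**
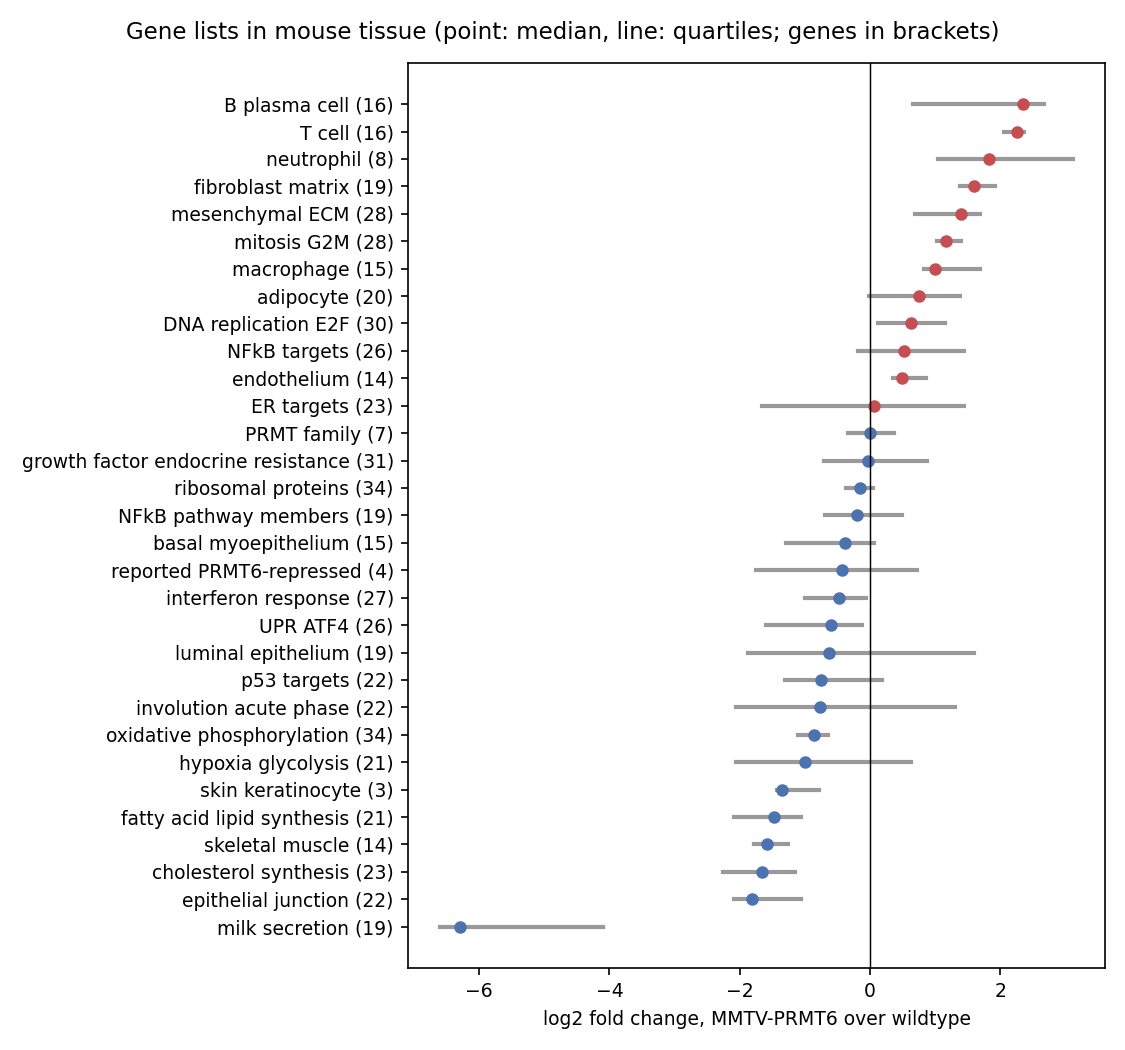
Log2 fold changes of the list members in the libraries labelled MMTV-PRMT6 against wildtype mice, as the median and the quartiles of each gene list. The milk list has the lowest median, and the lists of T cells and of B and plasma cells have the highest.

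Genes that move one way in the libraries labelled MMTV-PRMT6 and the other way after knockdown were sought by matching symbols between mouse and human. IGFBP4 was at 1.73 (SE 0.12) in the mouse and −1.91 (SE 0.05) in MCF-7, and at −0.68 in MDA-231. CNN2 was at 1.63 (SE 0.14) in the mouse and −1.23 (SE 0.05) in MCF-7, and the taurine transporter SLC6A6 at 1.66 (SE 0.13) in the mouse and −0.45 (SE 0.04) in MCF-7. In the other direction, the copper transporter SLC31A1 was at −3.19 (SE 0.19) in the mouse and 0.82 (SE 0.04) in MCF-7, the secreted STC2 at −2.04 (SE 0.15) in the mouse and 0.48 (SE 0.03) in MCF-7 and BOD1 at −1.22 (SE 0.10) in the mouse and 1.34 (SE 0.04) in MCF-7. The MCF-7 call of STC2 ended with the class term on few counts, as given above. The interleukin receptor subunit IL1RAP was at −2.12 (SE 0.12) in the mouse and 1.33 (SE 0.06) in MDA-231 and TMEM64 at −2.24 (SE 0.15) in the mouse and 2.34 (SE 0.07) in MDA-231. In MCF-7 TMEM64 went the way of the mouse, at −0.10 (SE 0.03, edgeR adjusted p 0.0251, 0.737 with the class term). IGFBP4 carries GTACTAC and SLC6A6 TGGTCCC in the human 3′ UTR. Opposite calls were fewer than independent lists give, 1556 against 1875 for MCF-7 and 1258 against 1526 for MDA-231. Calls in the same direction were more, 2226 against 1884 and 1834 against 1536.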

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

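The comparison of fibroblast with oxidative phosphorylation genes and the fits with the class term or against control 3 alone are tests chosen after the result was seen. NFKB1, a subunit of NF-κB, and CDKN1A, an inhibitor of the cell cycle, are taken up because the siRNA effect differed between the lines by the interaction test. MCF-7 minus MDA-231 was 0.60 (SE 0.07, edgeR adjusted p 6.6e-09, 0.0124 with the class term) for NFKB1 and −0.79 (SE 0.08, edgeR adjusted p 6.1e-10, 9.0e-04 with the class term) for CDKN1A, and the effect differed for 4434 genes in all (722 with the class term). In 100 splits of the siRNA labels within the lines, 1 gave as many, the real one, and the highest other gave 1739. The real labels thus gave more genes than the rearranged labels drawn. Such splits test for no siRNA effect and not for equal effects in the lines, so they cannot exclude chance for the difference. The library class is not excluded either. Other signals lay in alignments the comparisons did not use. In the MDA-231 knockdown 78.1% of alignments were not unique against 51.5% in its controls, and in the libraries labelled MMTV-PRMT6 54.7% of unique alignments lay outside annotated genes against 25.2% in wildtype.

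For the counts of changed genes, PRMT6 among them in both lines, the 10 splits of 6 libraries are too few for a share under 0.05, and 1 split, the real one, gave as many genes in each comparison. By edgeR the real count and the highest of the other splits were for MCF-7 7338 and 0 (381 at an unadjusted p under 0.05, 0 by limma-voom), for MDA-231 5647 and 0 (352 at an unadjusted p under 0.05, 0 by limma-voom) and for the mouse 9771 and 0 (94 at an unadjusted p under 0.05, 0 by limma-voom).

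The first pattern weighed is the set of genes changed in the human lines, from PRMT6 and HEXB down to small changes such as that of ESR1, against the library class. The knockdown was the low class in MCF-7 and the high class in MDA-231, so a class effect alone would turn genes in opposite directions, but of the genes called in both lines, such as HEXB, CBR1 and MCM2, 78.0% changed in the same direction (788 against 156 genes with the class term), which argues against the class for these. In MDA-231 the 4863 genes called against controls 1 and 2 had a median change against control 3 of 0.953 to 0.961 times that against controls 1 and 2, over the 3 knockdown libraries. The bound set beforehand would exclude the class on that ratio, but it was wrong in resting on the 1 library of control 3. For genes called in MDA-231 alone, class and siRNA are told apart only through that library, so the class is not excluded. In MCF-7 the class equals the siRNA group, and the 6610 genes tested differed between the MDA-231 controls by 0.0520 of their MCF-7 median, 55.7% with the same sign, which again rests on control 3, so for genes called in MCF-7 alone they cannot be told apart.

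The second pattern is the fall of milk genes such as Wap and Csn2 with the rise of T cell, B cell and fibroblast genes such as Lck, Pax5 and Dcn. A lower share of secretory epithelium alone would raise the markers of other cell types alike. The medians of B and plasma cell genes (2.35) and endothelium genes (0.48), the highest and lowest of the lists compared, lay 1.87 apart (SE 0.42). That SE comes from resampling the genes of a list, so it does not measure spread between mice, and taking the extremes favours a gap. Over the list genes the gap argues against a lower share as the whole cause. Leaving the 20 most abundant genes out of scaling gave 1.00 of the fibroblast median, but it moved the median log2 change of all genes by only −0.000773 and so decided nothing. The fibroblast median (1.60) and that of oxidative phosphorylation (−0.85) lay 2.45 apart (SE 0.13, again over list genes and not over mice). Over these genes the gap argues against a few abundant genes as the cause. Of 1453 olfactory and vomeronasal receptor genes 113 had any count, and their mean rise of 0.0143 CPM was 0.000726 of the median rise of 19.7 CPM of the genes called higher, which argues against genomic DNA. Both rises are in CPM that were not TMM-scaled. The stage of the gland, a change within the cell types and the MMTV-PRMT6 construct stay open and were not tested, since the wildtype labels give no stage. The milk list took 45.9% of gene counts in wildtype. It took 0.811 to 2.74% in the MMTV-PRMT6 libraries, which are labelled as taken after lactation. A difference of stage can therefore not be told apart from an effect of the construct.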

How the results depend on the processing

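The class term, high class, protein-coding and milk gene alternatives were tests chosen after the result was seen. PRMT6 was lower in the knockdown under each alternative run, at log2 −2.64 to −2.57 in MCF-7 and −1.98 to −1.88 in MDA-231, and mouse Prmt6 passed in none (0.11 to 0.32). With the class term 1986 genes changed in MCF-7 and 3864 in MDA-231, 722 differed between the lines and 788 were shared. Against control 3 alone 2659 changed in MDA-231 and 1327 were shared, with fewer libraries. Against a 1.2-fold change 2027, 1917 and 8281 passed in MCF-7, MDA-231 and the mouse, a stricter test by construction. Under the other alternatives these counts lay within 5747 to 7536 (MCF-7), above 3864 and up to 6122 (MDA-231), and within 8424 to 9763 (mouse), 3860 to 5110 (interaction) and 1811 to 2400 (shared). With a library left out the first 4 lay within 6320 to 7232, 4480 to 6072, 8424 to 9634 and 3915 to 4876. NF-κB targets in MCF-7 had a mean of 0.48 (adjusted p 0.0114) without the filter, 0.40 (adjusted p 0.0390) with the class term and 0.23 (adjusted p 0.00920) by fry. In the mouse fry gave NF-κB targets 0.13 (adjusted p 0.0240) and oestrogen receptor targets −0.37 (adjusted p 0.0141), and with a library left out the NF-κB mean lay within 0.0648 to 0.27. The class term widens errors (SE of PRMT6 in MCF-7 0.04 before and 0.12 after), so fewer calls do not by themselves show a class effect. For these counts and lists the cause was not tested. Same-numbered libraries share only a number: their deviations correlated by −0.0393 to 0.0218, and not every library correlated best with its own number. With the replicate block 7536 genes changed in MCF-7, 5643 in MDA-231, 8807 in the mouse and 4451 differed between the lines, and the mouse interferon list lost its call at −0.48 (adjusted p 0.0545) and p53 targets passed at −0.62 (adjusted p 0.0205). What depth limits was not separated from spread: simulated 1.5-fold changes were recovered at 35% in the mouse (coefficient of variation 16.2%) and 95% in MDA-231 (5.05%).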

Other observations

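The genes of opposite effect, the list tests on the interaction, the test of a 19-base duplex and the fits with the class term are tests chosen after the result was seen. CDK6, a kinase that pairs with D-type cyclins, was at −0.45 (SE 0.05) and 1.06 (SE 0.05) in MCF-7 and MDA-231, the WNT inhibitor DKK1 at 0.45 (SE 0.04) and −0.83 (SE 0.05), the actin regulator FAM49B at 0.59 (SE 0.04) and −0.59 (SE 0.05) and the transcription factor SOX4 at 0.22 (SE 0.03) and −0.95 (SE 0.07). The mitotic kinase NEK7 was at −0.29 (SE 0.05) and 1.27 (SE 0.05) and the secretory protein AGR2 at 0.17 (SE 0.04) and −0.97 (SE 0.10). With the class term the MCF-7 calls of SOX4 (from 0.22, SE 0.03, to 0.13, SE 0.09, adjusted p 0.446) and AGR2 (from 0.17, SE 0.04, to 0.14, SE 0.12, adjusted p 0.604) ended with smaller folds and wider errors, so their opposite directions rest on the fit without that term. In all, 595 genes were called in each line in opposite directions with a different effect by edgeR, and 242 of them also differed with the class term. As lists, DNA replication (14 of 30 members and 3 the other way, adjusted p 4.2e-10, 0.307 with an estimated correlation), cholesterol synthesis (9 of 24 members and 1 the other way, adjusted p 1.7e-04, 0.422 with an estimated correlation), interferon (7 of 32 members and 3 the other way, adjusted p 0.0149, 0.613 with an estimated correlation) and hypoxia genes (5 of 24 members and 2 the other way, adjusted p 0.0146, 0.472 with an estimated correlation) had the more positive effect in MDA-231. Ribosomal protein (9 of 35 members and 0 the other way, adjusted p 0.0146, 0.671 with an estimated correlation) and epithelial junction genes (6 of 22 members and 1 the other way, adjusted p 0.0374, 0.422 with an estimated correlation) had it in MCF-7. The other 13 lists, NF-κB targets (0.265) and oestrogen receptor targets (0.449) among them, did not pass by camera.

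The CPM of the RNAs named next are shares of all gene counts of a library, without TMM scaling. The nuclear RNA MALAT1 stood at 3263 to 4356 CPM in MCF-7 controls, 2246 to 2886 CPM in the MCF-7 knockdown, 4777 to 5247 CPM in MDA-231 controls and 4639 to 5430.1 CPM in the MDA-231 knockdown. RN7SK, which restrains transcription elongation, stood in the same order at 10959 to 12204, 9869.5 to 10881, 8946 to 9173 and 8568 to 9894 CPM. In the mouse Malat1 stood at 7217 to 9043 CPM in wildtype and 20022 to 24101 CPM in the libraries labelled MMTV-PRMT6, the ribosomal precursor Rn45s at 3947 to 4847 and 5435 to 8802 CPM, and transferrin (Trf), an iron carrier of milk, at 94213 to 121920.0 and 4142 to 9403 CPM. The milk list took 45.9% of gene counts in wildtype, which lowers the shares of all other RNAs there. These shares alone therefore do not show a rise of Malat1 or Rn45s, and their TMM-scaled values were not compared.

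HEXB, CBR1, PAICS and GPD1L, which fell in both lines, carry the word GTACTAC in the 3′ UTR, and BCAP31 and EIF4G2 carry TGGTCCC, while PARK7 and CNN2 carry neither. Of 1175 genes lower in both lines with a 3′ UTR, 170 (14.5%) hold GTACTAC against 4.90% in genes of like UTRs, a z of 15.6 where 100 random sets reached 5.06 at most, and 247 (21.02%) hold TGGTCCC against 12.9% (z 8.97). Among genes higher in both lines the highest z was 4.89, within the 5.19 of random sets.

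A hypothesis is that part of the genes lower in both lines, HEXB and CBR1 among them, may answer to seed matches of the siRNA rather than to the loss of PRMT6, since an siRNA also lowers RNAs that match its seed in the 3′ UTR. The test set first, whether the PRMT6 transcript holds more of the 20 most over-represented words than transcripts of like length and GC content, gave 4 words against a median of 2, with 29.5% of 2827 like transcripts holding as many, and so decided nothing. In the later test, the best 19-base stretch of the PRMT6 transcript (bases 164 to 182, coding sequence, hg38 chromosome 1, 107056842 to 107056860), with GTACTAC as the match of its guide seed and TGGTCCC of its passenger seed, had a summed z of 24.6, while the highest of 2827 like transcripts had 18.2. By the genes with either word, 32.8% against 17.0% in genes of like UTRs, the excess is 15.8 points of the genes lower in both. This counts only these exact words. Overlapping words were over-represented too, such as TACTACA (17.2% against 9.40%, z 9.68) and GGTCCCA (18.7% against 11.9%, z 7.69). Most of the genes lower in both, PARK7 and CNN2 among them, hold neither exact word, which does not place them outside seed effects. The siRNA sequence is not in the labels, so whether it matches this stretch stays open, and a second siRNA of another seed, or a rescue, would test it.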
